A study of Mus musculus with 2 samples.

How the data were processed

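RNA of the nucleoplasmic fraction was measured by total RNA-seq after ribosomal RNA depletion in 2 libraries of mouse macrophages grown from bone marrow (strain C57BL/6J) that had received Lipid A (40 min, 100 ng/ml). Per the labels, the libraries are biological replicates 1 and 2 of 1 group. They carry the same donor identifier, so the spread between them may hold less than the full spread between animals. Replicate 1 was made from 1 µg and replicate 2 from 500 ng of RNA, so RNA input and replicate cannot be told apart. Fragments were selected for a size range of 250 to 400 in both. Untreated cells, other times and other cell fractions were not analysed here.

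Each library had a gene table and a transcript table made by the authors from an alignment to the transcriptome, and a further transcript table made from the FASTQ files without that alignment. These are called alignment-based and FASTQ-derived. The genome build was mm10 and the annotation GENCODE M21 per the labels deposited with the tables. The aligner, the quantifiers, their versions and their strand setting are not given in the sources used here. Per the file headers, the alignment-based tables give expected counts, and the FASTQ-derived table gives estimated counts, neither of which need be whole numbers. The deposited TPM values are scaled to the same total over every feature of a table, spike-in and phiX sequences included, after correction for effective length. The deposited FPKM values are scaled per kilobase and by the assigned fragments of the library. A posterior mean TPM with lower and upper bounds of a credibility interval stood beside the TPM in the authors' alignment-based tables. These bounds cover counting and read assignment within 1 library, are centred on the posterior mean and can lie wholly below the TPM of an abundant gene.

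All 55536 gene identifiers and 141862 of the 168207 transcript identifiers of the alignment-based tables matched the annotation. The remaining identifiers were 26248 purely numeric ones, 96 ERCC spike-in sequences and the phiX control genome, and these were left out of library sizes and comparisons. phiX took 131900 expected counts (0.672%) in replicate 1 and 36128 (0.196%) in replicate 2. Coordinates are 1-based positions on mm10. GC content and sequence came from the GENCODE M21 transcripts, which covered 55450 genes.

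The alignment-based totals were 19630046 expected counts in replicate 1 and 18434601 in replicate 2. The FASTQ-derived totals were 26929533 and 33536257, phiX included. Despite the shared size range, fragments were longer in replicate 2. The mean fragment, taken as length minus effective length of long models, was 206 nt in replicate 1 and 230 nt in replicate 2 by the alignment-based tables. By the FASTQ-derived tables it was 164 and 236 nt. The median detected protein-coding gene had 418 and 396 expected counts, and its credibility interval spanned 30.1% and 32.0% of its TPM. Where a gene had 0 counts, its upper limit was taken as 3 counts per library, although the deposited credibility interval can reach higher. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

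With 1 group, no contrast between conditions existed, so levels were described within the group. A gene was called detected at a TPM of at least 1 in both replicates. The gene lists, the rule for named genes, the comparisons and their alternatives were fixed before the data were examined. Some tests of technical explanations were chosen later, as the closing section states. The 25 lists held 317 genes, and all were found. They covered immediate-early genes, early inflammatory genes, NF-kB feedback genes, late inflammatory genes, interferon response genes and the TLR4 pathway. Further lists held markers of macrophages, neutrophils, T cells, B cells, NK cells, dendritic cells, mast cells and basophils, erythroid cells, megakaryocytes, fibroblasts and endothelial cells. The others held nuclear long non-coding RNAs, snoRNA host genes, structural non-coding RNAs, mitochondrial mRNAs, ribosomal protein genes, cytosolic housekeeping genes, proliferation genes and Y-linked genes. A list's median TPM was placed among the medians of 10000 random lists of the same size. These were drawn from the detected protein-coding genes, or from all protein-coding genes for the cell type markers. The percentile describes these libraries and is no p-value, because genes are not replicates. On the log scale, levels were log2(TPM + 1), and the gap between early and late lists was the difference of their medians.

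Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3. The common dispersion was estimated for 1 group with TMM scaling over genes with a mean expected count of at least 10. Its square root is the biological coefficient of variation. Its error came from resampling genes. The ratio between replicates was the log2 ratio of TMM-scaled CPM with a prior count of 2, and for a list or RNA class the median of all genes tested was subtracted. A list's median ratio was placed among 10000 random lists whose members were drawn from the 100 genes nearest in mean expression to each list member. Each side of that ratio is 1 library, so it has no replicate check and no p-value is given. A chi-square of the counts over genes was used only to ask whether the libraries could be 1 library deposited under both names. The 2 transcript quantifications were compared over 141767 transcripts on the log2(TPM + 1) scale. Transcripts were called apart at over 2-fold in the same direction in both replicates. The share of retained-intron models was taken over the transcripts of protein-coding genes, and, as a step added after the values were seen, over genes with such a model only. Sequence shared between annotated transcripts was counted as 31-mers on either strand, for models chosen after their values were seen. Small RNA models were also summed into families, linked where they shared at least 50% of the 31-mers of the smaller one or overlapped on 1 strand, a step likewise chosen after the values were seen. The partners of the models, Cd3d, and genes named only in the last section, were also chosen then. Other work used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

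The dispersion estimate was tested on simulated counts with the real means and library sizes of 14527 genes. Simulated coefficients of variation of 0.1, 0.2 and 0.4 came back as 0.102, 0.196 and 0.398. Genes raised or lowered by 2 on the log2 scale came back with median ratios of 1.99 and -2.01. In a simulation of 5000 genes, 40 lists of 20 members with no shift fell outside the central 95% of random lists in 7.5% of cases when matched on size and in 5% when matched on expression. With a shift of 1 SD, 100% fell outside in both.

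Genes were named by rule. The rule took the 4 highest members of each list and up to 3 members not detected, the 15 highest protein-coding and 10 highest other genes, and the 10 highest and 10 lowest ratios among genes with a mean expected count of at least 100. It also took the 5 transcripts in each direction with the widest gap between quantifications. Alternatives were FPKM, posterior mean TPM, TPM rescaled over protein-coding genes, the FASTQ-derived values, omission of genes with an effective length under 200, pseudocounts of 0.1, other detection thresholds, DESeq2 1.42.0 size factors, library size alone, other count filters, a prior count of 0.5, and each replicate left out. Genes that overlap, lie antisense to each other or have near-identical copies were treated as uncertain, since reads may be split between them.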

Results

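Lipid A, the part of lipopolysaccharide that the receptor TLR4 recognises, was given at 100 ng/ml for 40 min to macrophages differentiated from mouse bone marrow. The nucleoplasmic fraction is meant to hold RNA that is in the nucleus and not bound to chromatin, and its purity was not measured here. Ribosomal RNA was depleted from it before sequencing. Both libraries, biological replicates 1 and 2, belonged to this 1 group. They held 19630046 and 18434601 expected counts, phiX included. Values below are means ± SD over both replicates (n = 2), and TPM is the authors' alignment-based estimate. No unstimulated library was analysed here, so the values are levels and not responses.

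The first question was how abundant the known TLR4 response genes were in the nucleoplasmic fraction. Of the 55 immediate-early, early inflammatory and NF-kB feedback genes listed, 54 were detected and 51 had a mean TPM of at least 10. The early inflammatory list had a median of 297 ± 50.5 TPM. It was led by the cytokine gene Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) at 1097 ± 235 TPM. The neutrophil-attracting chemokine Cxcl2 followed at 1005 ± 346, the cytokine Il1b at 767 ± 178 and the co-stimulatory ligand Tnfsf9 at 645 ± 157. The 1 member not detected was Cxcl3, at 0.90 ± 0.45 TPM.

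The 14 NF-kB feedback genes were all detected, with a median of 88.6 ± 17.5 TPM. Among them Tnfaip3, which encodes the ubiquitin-editing inhibitor A20, reached 763 ± 180 TPM (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657). The gene of the inhibitor IκBα, Nfkbia, reached 621 ± 301, that of the nuclear IκB protein, Nfkbiz, 495 ± 120.2, and Tnip3, whose product binds A20, 237 ± 104. The 23 immediate-early genes were all detected as well, with a median of 87.6 ± 30.4 TPM. The phosphatase gene Dusp1 led at 440.0 ± 168 TPM, followed by Zfp36, whose product destabilises cytokine mRNAs, at 350.2 ± 106, the transcription factor gene Klf6 at 342 ± 103 and the stress gene Gadd45b at 301 ± 121. For comparison, the median detected protein-coding gene had 7.42 TPM and the gene at the 99th percentile 327 TPM. All 3 medians lay at the 100th percentile of random lists of detected genes. They stood 5.13 ± 0.07, 3.42 ± 0.02 and 3.42 ± 0.18 above the median detected gene on the log2 scale, for the early inflammatory, feedback and immediate-early lists.

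Most of the pathway that carries the signal was present at ordinary levels. Of 22 TLR4 pathway genes 20 were detected, with a median of 12.5 ± 3.32 TPM at the 92.3 percentile of random lists. The co-receptor gene Cd14 stood out at 494 ± 107 TPM. The kinase gene Irak2 had 96.3 ± 18.4, the transcription factor gene Irf3 83.7 ± 18.8 and the kinase gene Tbk1 72.9 ± 13.2. The adaptor gene Tirap, at 0.765 ± 0.0071 TPM, and Tab3, at 1.32 ± 0.59, were not detected in both replicates.

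The next comparison set genes known to respond early against those known to respond late. Of 16 late inflammatory genes 9 were detected, and the median of all 16 was 1.98 ± 0.085 TPM, at percentile 0 of random lists of detected genes. Such lists hold only genes of at least 1 TPM, so a list with undetected members falls low largely by construction. Against all protein-coding genes, the lower megakaryocyte median of 1.13 TPM lay at percentile 65.7. The highest was Acod1, whose enzyme makes itaconate, at 125 ± 27.2 TPM. The chemokine Ccl5 had 63.5 ± 16, the interleukin-18 inhibitor Il18bp 19.6 ± 5.32 and the collagenase gene Mmp13 17.6 ± 5.86. In contrast, the nitric oxide synthase gene Nos2 had 0.13 ± 0.071 TPM and the iron-carrier binding Lcn2 0.80 ± 0.17. Il12a had 0 counts in both libraries. Its upper limit at 3 counts was 0.157 TPM in replicate 1 and 0.121 in replicate 2, but its credibility intervals reached 0.633 and 0.505. The interferon response list was intermediate, with 20 of 22 genes detected and a median of 35.3 ± 12.4 TPM at percentile 99.99. Its highest members were the GTPase gene Gbp5 at 199.6 ± 52.0 TPM, Oasl2 at 156 ± 10.7, the antiviral gene Rsad2 at 155 ± 37.8 and the chemokine Cxcl10 at 126 ± 36.3. Cxcl9 and Cxcl11, chemokine genes of the same family, had 0.275 ± 0.26 and 0.595 ± 0.32 TPM.

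The median of the 3 early lists together exceeded that of the late inflammatory list by 5.22 ± 0.31 on the log2(TPM + 1) scale, a 37.2-fold gap. It was 5.44 in replicate 1 and 5.0 in replicate 2. Against the interferon list the gap was 1.62 ± 0.24, or 3.08-fold. Both gaps were larger than the spread between replicates. With only members of at least 1 TPM in either replicate the first gap was 2.88, so much of it came from late genes near 0. The plot of list members shows these levels gene by gene.

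**Figure D1:**
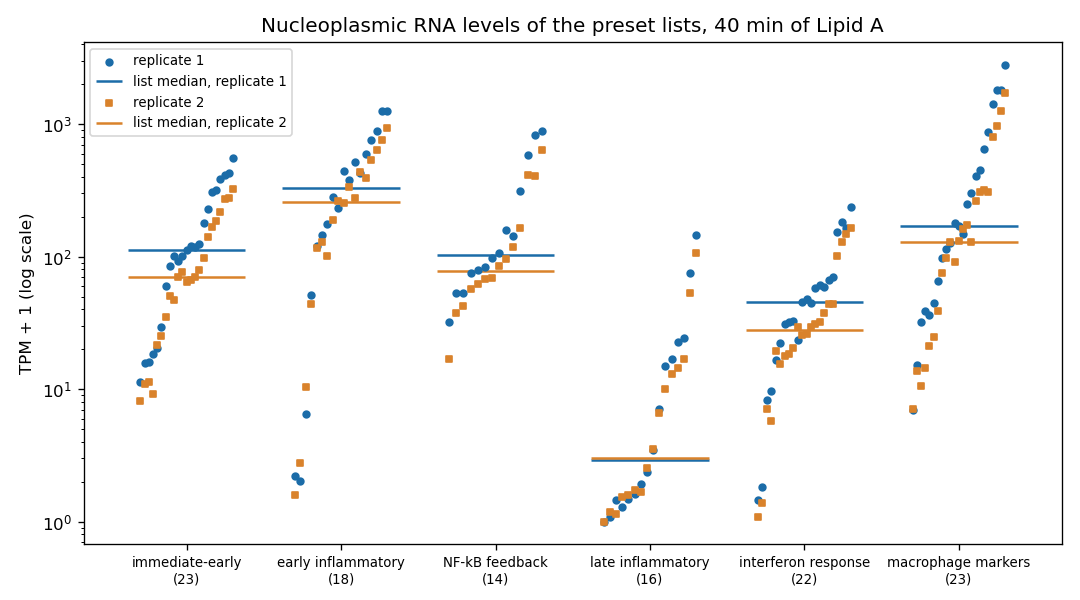
TPM + 1 on a log scale for each member of 6 gene lists, ordered within a list by mean TPM, with circles for replicate 1, squares for replicate 2 and a horizontal line at each list's median per replicate. The medians of the 3 early lists lie near 100 TPM or above in replicate 1, while that of the late inflammatory list lies at 1.92 TPM in replicate 1 and 2.04 in replicate 2.

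The cell type markers asked what cells the RNA came from. All 23 macrophage markers were detected, with a median of 150 ± 29.7 TPM at the 100th percentile of random lists of protein-coding genes. The glycoprotein gene Gpnmb had 2253 ± 750.2 TPM (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), the lysozyme gene Lyz2 1542 ± 393, and the lysosomal protease genes Ctsb and Ctsd 1397 ± 601 and 1111 ± 449. Of 67 markers of 10 other cell types, 8 were detected and 3 had a mean of at least 10 TPM, while 23 had 0 counts in both libraries. Those above 10 TPM were the T cell co-stimulatory receptor Cd28 at 70.7 ± 18.9, the granulocyte growth factor receptor Csf3r at 64.5 ± 1.12 and the platelet chemokine Pf4 at 32.7 ± 3.58 TPM. Other markers of the same cells were low. The T cell surface gene Cd5 had 2.56 ± 1.27 TPM, the neutrophil gene S100a9 1.11 ± 0.33, and Cd3e, Cd3g and Elane had 0 counts. For Elane that allows up to 0.180 and 0.139 TPM in the libraries. The FASTQ-derived tables gave Cd3g 0.154 and 0.234 TPM, and gave Cd3d 2.38 and 4.28 against an alignment-based mean of 0.085 ± 0.021.

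Median levels of these 10 lists were 1.13 TPM for megakaryocytes, 0.665 for neutrophils, 0.383 for dendritic cells, 0.045 for B cells, 0.0425 for T cells, 0.040 for endothelial cells, 0.0325 for erythroid cells, 0.0225 for fibroblasts, 0.0175 for mast cells and basophils and 0 for NK cells. Their percentiles among random lists of protein-coding genes ran from 10.95 for NK cells to 65.7 for megakaryocytes, so none stood above such lists. Most protein-coding genes were not detected, so this percentile says little about low lists, and even the NK cell list with a median of 0 was at 10.95.

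The composition of the fraction was described by RNA class. Of 22028 protein-coding genes 8810 (40.0%) were detected, and 10765 of 55536 genes of any class. The highest non-coding levels by TPM were those of short structural RNAs. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, had 235433 ± 44889 TPM (ENSMUSG00000065037, chromosome 9, 78175303 to 78175633). Rpph1, the RNA of ribonuclease P, had 76940 ± 57511 TPM, the ribozyme model of Rmrp 59704 ± 27969, and Rn7s1 and Rn7s2, RNAs of the signal recognition particle, 38774 ± 10701 each. The long nuclear RNA Malat1 had 24466 ± 3364 TPM (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672), the paraspeckle RNA Neat1 1501 ± 689.6, the X inactivation RNA Xist 343 ± 94.1 and Lncpint 236 ± 62.8. By expected counts, which are not divided by length, Malat1 was above Rn7sk, with 2505560 and 1991347 against 565963 and 815583. Some other long nuclear RNAs were scarce, and the list of 19, of which 15 were detected, had a median of 4.96 ± 0.83 TPM at percentile 13.3. This list stood 0.48 below the median detected gene on the log2 scale but 0.31 above it, at percentile 75.0, with FASTQ-derived values. Meg3 had 0 counts and Tsix, which lies antisense to Xist, 0.12 ± 0.057 TPM.

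Mitochondrial mRNAs were all detected, with a median of 3009 ± 769 TPM, with mt-Atp8 at 14328 ± 4138 and mt-Co1 at 11089 ± 3862. They took 4.54% of expected counts, so the fraction held RNA from outside the nucleus. How far such RNA adds to the levels of other genes was not tested. The model of mt-Atp8 is short, and mt-Co1 was above it in the FASTQ-derived tables (5679 and 4015 against 2269 and 3969 TPM) and by expected counts (397973 and 314868 against 6910 and 8816). The 15 cytosolic housekeeping genes had a median of 58.5 ± 12.9 TPM and included the ferritin genes Fth1 at 727 ± 279 and Ftl1 at 643 ± 206 and the actin gene Actb at 568 ± 139.9. The 25 ribosomal protein genes had 28.7 ± 4.74 TPM, with Rpl10 highest at 96.2 ± 35.7. These 3 lists and the 11 structural non-coding RNAs, with a median of 278 ± 229 TPM, were at the 100th percentile. The 10 snoRNA host genes, at 8.51 ± 4.14 TPM and percentile 58.2, were not, although Taf1d had 90.4 ± 18.8 and Gas5 43.5 ± 13.7 TPM. The highest nuclear-encoded protein-coding genes were the lysosomal Psap at 3154 ± 1450.5 TPM, the receptor gene Lilr4b at 2275 ± 368 and Gpnmb.

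By TPM, protein-coding genes took 26.9% ± 6.14 of the libraries, misc_RNA genes 31.4% ± 6.61, snRNA genes 14.3% ± 3.17 and ribozymes 13.7% ± 8.55. By expected counts, protein-coding genes took 72.9% ± 0.48, lincRNA genes 15.7% ± 1.77 and misc_RNA genes 4.59% ± 1.40. The measures differed because TPM divides by an effective length that is small for short RNAs, and without genes of effective length under 200 the protein-coding share of TPM was 79.5%. At a threshold of 5 TPM 4907 protein-coding genes were detected. For all genes the number was 5562 at 5 TPM and 16356 at 0.1 TPM.

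**Figure D2:**
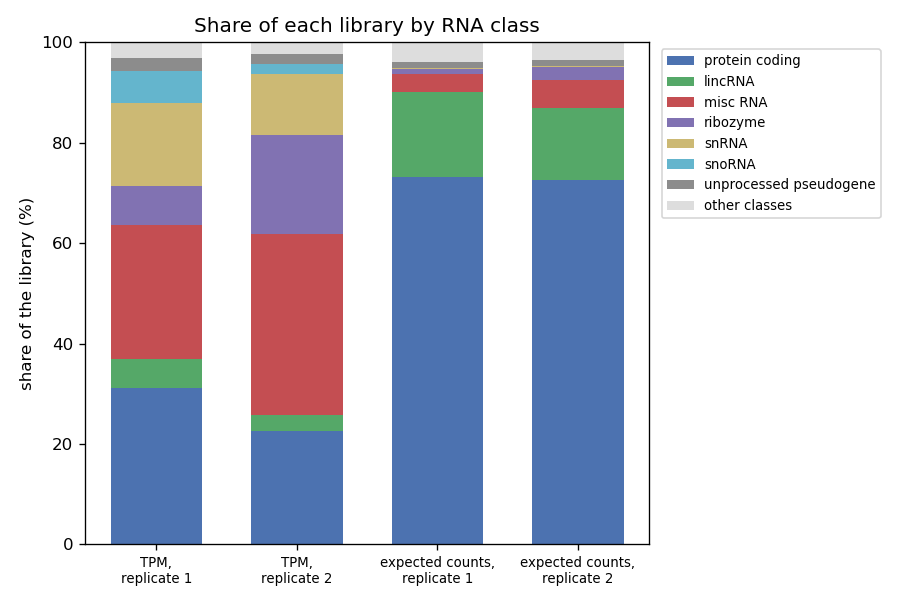
Stacked bars of the percentage of each library taken by each RNA class, by TPM in the left pair of bars and by expected counts in the right pair, with 1 bar per replicate. Protein-coding genes take 31.3% and 22.6% of TPM in replicates 1 and 2 but 73.3% and 72.6% of expected counts.

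Nuclear RNA can hold incompletely spliced transcripts, so the share of retained-intron models, annotated transcripts that keep an intron of their gene, was examined. Over all protein-coding genes these models took 19.8% ± 0.73 of TPM, and 24.7% ± 0.32 without the mitochondrial genes, which have none. By TPM the share was 37.0% ± 0.64 in the TLR4 pathway, 29.5% ± 1.34 in the NF-kB feedback list and 27.1% ± 0.60 in the interferon list. It was 18.2% ± 2.55 for early inflammatory, 17.7% ± 0.37 for immediate-early and 14.7% ± 1.07 for late inflammatory genes, and 9.54% ± 0.93 for macrophage markers. By expected counts the order differed. The feedback list was highest at 26.6% ± 0.56, followed by the TLR4 pathway at 20.3% ± 0.25, the interferon list at 19.4% ± 0.05 and early inflammatory genes at 19.0% ± 2.79. Immediate-early genes had 10.2% ± 0.43, macrophage markers 4.66% ± 0.42 and late inflammatory genes 3.98% ± 0.18, against 16.9% ± 0.32 for all protein-coding genes without the mitochondrial ones. Of 46 detected members of the response and macrophage lists with such a model, 9 had over 50% of their TPM in it in both replicates, among them Tnip3 at 82.3% ± 2.70, Dusp1 at 73.4% ± 4.69, Ccl5 at 60.5% ± 5.70, Oasl2 at 59.2% ± 0.55 and Tnfaip3 at 52.3% ± 1.23. Of these 9, 8 were over 50% in the FASTQ-derived tables as well, while Tnfaip3 had 42.8% and 43.5%. Cxcl2 had 45.8% ± 0.39. The protease gene Ctsd had 1.07% ± 0.33 and was among 7 genes under 10% in both. Annotation partly sets the order of the lists, since 11 of 14 feedback, 16 of 22 pathway and 12 of 20 protein-coding interferon genes have such a model, but 9 of 23 macrophage, 7 of 23 immediate-early and 3 of 16 late inflammatory genes. Over genes with a model only, the feedback list had 38.2% ± 2.49 of TPM, the pathway 39.0% ± 0.59, the interferon list 40.5% ± 0.33, early inflammatory genes 39.8% ± 3.11 and immediate-early genes 37.2% ± 0.70, while the 3 late inflammatory genes had 60.3% ± 5.73. By expected counts these genes gave 38.5% ± 0.38 for the feedback list, 22.9% ± 0.19 for the pathway, 31.6% ± 0.048 for the interferon list, 40.8% ± 3.97 for early inflammatory, 22.8% ± 0.12 for immediate-early and 68.1% ± 5.51 for late inflammatory genes. Of the 3 late inflammatory genes with a model only Ccl5, at 60.5% ± 5.70 of TPM, was detected, so the late values rest on Ccl5 and describe no list. The order of these lists thus depended on the measure and on the genes included. Macrophage markers with a model were lowest, at 14.2% ± 1.18 of TPM and 5.80% ± 0.47 of counts, against 35.1% ± 0.76 and 24.4% ± 0.59 for all such genes. Over all members, ribosomal protein genes had 23.3% ± 2.15 and housekeeping genes 22.8% ± 2.98, so response genes were not alone in this. Short-read assignment among overlapping models is uncertain, and the FASTQ-derived tables gave 22% for all protein-coding genes.

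**Figure D3:**
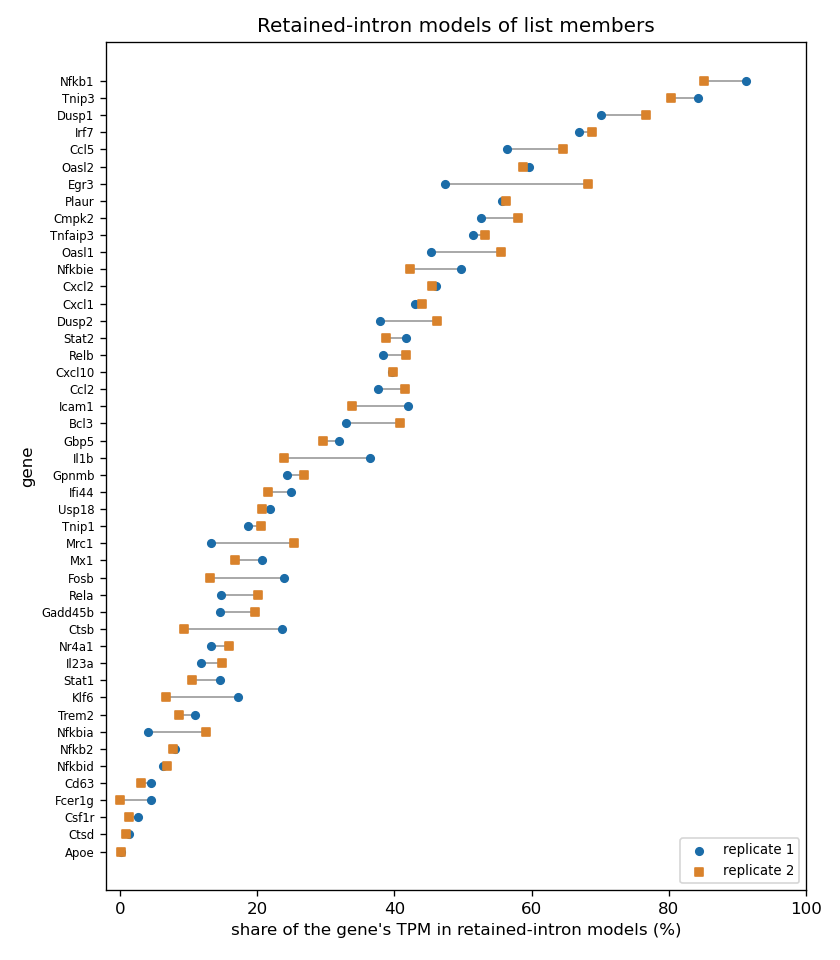
Percentage of a gene's TPM assigned to retained-intron models for 46 detected list members, with a circle for replicate 1, a square for replicate 2 and a line between them. Genes run from Nfkb1, Tnip3 and Dusp1 at the top to Ctsd and Apoe near 0%.

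The replicates were then compared with each other. Several small RNAs differed widely. Rpph1 had 92143 expected counts in replicate 1 and 323271 in replicate 2, a log2 ratio of 1.91, and Rn7sk had a ratio of 0.63. The list of structural non-coding RNAs had a median ratio of 0.75, at the 100th percentile of lists matched on expression. That median is the common value of Rn7s1 and Rn7s2, copies that both belong to the list. Over the 20 genes tested of the misc_RNA class, to which Rn7sk belongs, the median was -0.16, with 13 lower in replicate 2. Summed over its genes, however, the class took 3.60% of expected counts in replicate 1 and 5.59% in replicate 2. Of the spliceosomal and nucleolar RNAs, 29 of 30 snRNA models and 29 of 36 snoRNA models were lower in replicate 2, with medians of -0.83 and -1.48. Many of these models are copies that share reads. Summed into families of shared sequence or position, all 5 snRNA families and 25 of 27 snoRNA families were lower in replicate 2, with medians of -1.26 and -2.38. The snoRNAs Snora73b and Snora73a, which guide ribosomal RNA processing, had 524 and 457 expected counts in replicate 1 and 30.1 and 27.5 in replicate 2. Reads of Rmrp were divided between its ribozyme model, with a log2 ratio of 1.1, and a lincRNA model over the same positions, and both summed gave 0.50.

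Among protein-coding lists the immediate-early genes had a median log2 ratio of -0.25 (18 of 23 lower in replicate 2, percentile 0 of matched lists), macrophage markers -0.24 (17 of 23 lower, percentile 0) and interferon response genes -0.17 (17 of 22 lower, percentile 0.09). Nfkbia, with 23974 and 14473 expected counts, had a ratio of -0.63. Ribosomal protein genes had a median of 0.16 (percentile 98.4). Early inflammatory genes had 0.22 (11 of 18 higher, percentile 99.3), but this call was lost under other settings. With at least 100 counts their median was 0.08 at percentile 81.4. With a ratio of TPM + 1 it was -0.10 at percentile 85.7 of matched lists, a setting in which the feedback and housekeeping lists also had negative medians, -0.12 and -0.03, although they lay at percentiles 64.9 and 93.6 of matched lists. NF-kB feedback genes had 0.03, late inflammatory and TLR4 pathway genes 0.05 each, and the percentiles of these 3 lay between 41.7 and 68.6. Mitochondrial and long nuclear RNA lists had -0.03 each, snoRNA host genes -0.18 at percentile 6.98 and housekeeping genes 0.11 at percentile 84.3. With a ratio of TPM + 1 the snoRNA host genes had -0.38 at percentile 0.37.

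Several of the genes furthest apart between replicates share sequence with another model. Gm37376, a model antisense to Malat1 that lies within it, had 5541 expected counts in replicate 1 and 0 in replicate 2. Zbed6, an intronless gene whose sequence lies wholly within a Gm38394 transcript, had 740.2 and 0, and the pair summed had a log2 ratio of 0.12. B430305J03Rik, with 0 and 367 counts, lies antisense within Rap2b. An Nnt model, for which shared sequence was not examined, had 44.1 and 279 counts, and both Nnt models summed had a ratio of 0.22. These genes are reported as uncertain. By contrast Cnih1, whose product helps export proteins from the endoplasmic reticulum, had 133 and 409 counts and shares 13.2% of its 31-mers with an antisense model. Shared sequence was not examined for the cell-cycle inhibitor gene Cdkn1c, with 80 and 244 counts, or for the peptide transporter gene Slc15a2, with 309 and 50.

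Over 14527 genes the biological coefficient of variation was 0.176 (resampling SD 0.0044), and 723 genes (4.98%) were over 2-fold apart. That number was 101 of 8653 genes with at least 100 counts, 2542 of 22499 with no filter and 243 with a ratio of TPM + 1. Across genes, log2 TPM correlated at Pearson r = 0.977 and Spearman rho = 0.922, with the reservation that genes are not independent replicates. The chi-square of the counts was 43.2 per degree of freedom, so the libraries differed by far more than sampling noise. The TPM of the median detected protein-coding gene was 0.49 lower in replicate 2 on the log2 scale, a difference that enters the SD of each TPM above.

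**Figure D4:**
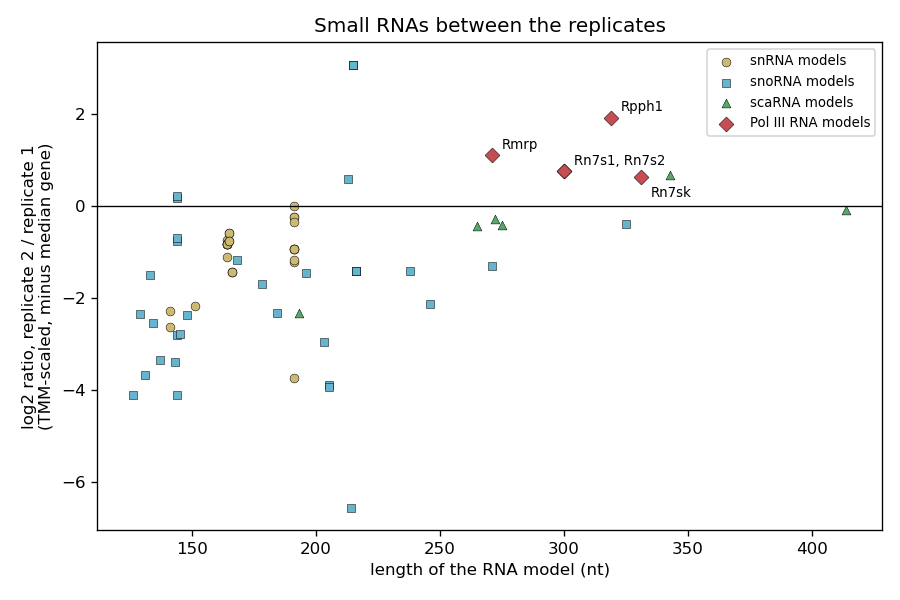
Log2 ratio of replicate 2 to replicate 1 (TMM-scaled counts, minus the median gene) against the length of the RNA model in nucleotides, for snRNA, snoRNA, scaRNA and the 5 Pol III RNA models. The Pol III models lie between 0.63 and 1.91, while most snRNA and snoRNA models lie below 0.

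Each library had been quantified by the authors along a pair of routes, and these were compared transcript by transcript. Several short RNAs were present in 1 quantification only. The miRNA models Gm23935, Gm24245 and Gm24270, of 57 nt and identical in every 31-mer, had 149156 TPM each in replicate 1 and 71387 in replicate 2 in the FASTQ-derived tables and 0 in the alignment-based ones. The processed pseudogenes Gm12895 and Gm12896, which share 99% of their 31-mers, had 72878 TPM each in replicate 1 and 133659 and 133902 in replicate 2, also against 0. In the other direction, Gm10222, a chromosome 1 pseudogene whose 31-mers all occur in mt-Nd4l, had 3203 and 6066 TPM in the alignment-based tables and 0 in the FASTQ-derived ones. Gm10925, whose 31-mers all occur in mt-Atp6, had 5793 and 4192 TPM against 22.1 and 0.0469. A transcript of the interferon-inducible gene Rnf213 had 56.4 and 47.5 TPM against 0.

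Across 141767 transcripts the mean Pearson r was 0.765 ± 0.025 and Spearman rho 0.735, both across transcripts, which are not independent replicates. Over 2-fold higher in the FASTQ-derived tables in both replicates were 5728 transcripts, and 2465 were lower. The sum of 8193 was 24291 with a pseudocount of 0.1 and 13516 without replicate 2. The TPM scales of the routes were unlike. In replicates 1 and 2 miRNA models took 46.9% and 23.5% of FASTQ-derived TPM but 0.011% and 0.0056% of alignment-based TPM. With both rescaled over 101652 transcripts of protein-coding genes, 10426 were higher and 1397 lower in the FASTQ-derived tables, so these numbers depend on the scale. Summed over protein-coding genes and rescaled to them, the mean Pearson r was 0.934 ± 0.0087. Even so, 2746 of these 21951 genes (12.5%) were over 2-fold apart, 2730 of them higher and 16 lower in the FASTQ-derived tables.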

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

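The tests of RNA length, of summed copies, of count-matched genes and of ribosomal protein genes, and the sums over small RNA families, were chosen only after the result was seen, and the others before. The design has 1 group, so no biological explanation was tested for any pattern below.

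Sequences outside the measured genes had counts above the limit of 3 that a count of 0 allows. The phiX control genome, added to sequencing runs, had 131900 expected counts in replicate 1 and 36128 in replicate 2, and 146755 and 43784 in the FASTQ-derived tables. Features with purely numeric identifiers had 20 and 19 expected counts. ERCC spike-in sequences had 10 and 35 counts in the FASTQ-derived tables and 0 in the alignment-based ones.

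The first pattern weighed was the higher level of 5 Pol III RNA models, for Rn7sk, Rpph1, Rmrp, Rn7s1 and Rn7s2, and the lower level of snRNAs and snoRNAs in replicate 2. GC content was argued against, since the median ratio of the 5 models was 0.87 (SD 0.58) after subtraction of the GC trend of protein-coding genes and 0.75 before. Both medians are the value of Rn7s1 and Rn7s2, copies with equal counts. After subtraction Rn7sk had 0.70, Rpph1 2.13 and the ribozyme model of Rmrp 1.21, although both Rmrp models summed gave only 0.50 before it. Whether a trend of protein-coding genes holds for RNAs this short was not tested. Reads shared between copies were argued against by a ratio of 0.81 for all 585 misc_RNA, ribozyme and Rmrp models summed. Length stays open. The 6 scaRNA and snoRNA models of 250 to 350 nt, the length of the Pol III models, had a median of -0.40 within their spread (SD 0.62), with 5 of 6 lower. No snRNA was among them, and scaRNA families had a median of -0.37 against -2.38 for snoRNA families, so length and class are confounded here. Medians over families of models summed were -3.29 under 130 nt (2 families), -2.34 at 130 to 200 nt (22 families), -2.24 at 200 to 250 nt (7 families) and -0.42 at 250 to 350 nt (6 families). Over single models the medians in these bins were -3.23, -1.03, -1.42 and -0.40, which do not run in order of length. RNA input, 1 µg against 500 ng, stays open and cannot be told apart from the replicate.

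The next pattern was an excess of FASTQ-derived over alignment-based counts for genes that lie opposite a gene with at least 100 times their counts. For 201 such genes the log2 count ratio exceeded that of genes with no overlap by 0.96 (SD 0.20), which left open whether that quantification ignored strand, since the bound set was 1. Overlap on the same strand gave 0.93 over 78 genes, so overlap whatever the strand also stays open. Against genes matched on count and class the excess was 0.36 (SD 0.17) opposite an abundant gene, with 113 of 201 above 0 in both replicates, and 0.17 (SD 0.12) on the same strand, with 38 of 78, so low counts may account for part of both. Single pairs differed, as Gm37376 opposite Malat1 had 22571 and 67778 FASTQ-derived counts while Tsix opposite Xist had 29.4 and 24.1. In replicate 1 Gm37376 had 5540.58 alignment-based counts, and its sum with Malat1 was 2511101, a whole number. Alignment-based counts may thus be shared across strands too. In that case the comparison cannot decide on strand, since neither route would respect it.

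The last pattern was the lower ratio of macrophage, immediate-early and interferon lists and the higher ratio of the early inflammatory list in replicate 2, where the call for the latter was lost with a ratio of TPM + 1, at -0.10 and percentile 85.7 of matched lists. After subtraction of the joint trend with GC content and length the medians were -0.20 for macrophage markers, -0.18 for immediate-early, -0.20 for interferon response and 0.20 for early inflammatory genes. Each stayed outside 95% of matched random lists, at percentiles of 0.07, 0.07, 0.03 and 99.7, which argues against that trend as the whole cause. More cytoplasmic RNA in replicate 1 would place ribosomal protein genes lower in replicate 2. Their median was instead 0.16, at percentile 98.4 of matched lists, which goes the other way. Single genes went both ways, however, 14 of 25 higher and 11 lower, and the median lay within their spread (SD 0.25 over genes). More cytoplasmic RNA in replicate 1 therefore stays open. RNA input and a small difference in stimulation or harvest between the cultures stay open and were not tested.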

How the results depend on the processing

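All of these alternatives were chosen before the result was seen. Lists above random lists in level numbered 8 or 9 and those below 3 or 4 under each alternative, and in ratio 2 to 4 and 3 or 4. The 3 lists below in level in the main setting were set against detected genes only, which places lists with undetected members low largely by construction. The gap between the early lists and the late inflammatory list was 5.63 with TPM rescaled over protein-coding genes, 4.47 with FASTQ-derived values, 5.75 with a pseudocount of 0.1 and 2.88 with members of at least 1 TPM only, the last because fewer late genes entered; it was 5.0 to 5.44 with a replicate left out. Against the interferon list it ran from 1.46 to 1.79 in that way. Detection at 5 TPM gave 4907 protein-coding and 5562 genes of any class and at 0.1 TPM 16356 of any class, by construction, and 1 replicate alone gave 8899 to 9596 and 11000 to 12351. The protein-coding share was 72.9% by expected counts and the misc_RNA share 4.59%, because expected counts are not divided by length. Removal of genes with an effective length under 200 gave 79.5% and 0%, because the misc_RNA genes with a level were among those removed. With a replicate left out the protein-coding share was 22.6% to 31.3% and the misc_RNA share 26.7% to 36.0%. The coefficient of variation was 0.154 with at least 100 counts and 0.144 for protein-coding genes. Genes over 2-fold apart numbered 2542 with no filter, 101 with at least 100 counts and 243 with a ratio of TPM + 1. Between quantifications r was 0.562 for transcripts of at least 1 TPM, 0.822 without transcripts under 200 nt and 0.747 to 0.782 per replicate, and transcripts apart numbered 24291 with a pseudocount of 0.1 and 11557 to 13516 per replicate. The retained-intron share was 22% in FASTQ-derived tables, 15.8% by counts and 19.3% to 20.4% per replicate. The ratio of the early inflammatory list lost its call with a ratio of TPM + 1, at -0.10 and percentile 85.7 of matched lists, and with at least 100 counts, at 0.08 and percentile 81.4. Where no cause is named, the cause was not tested. Further values of single lists and classes were judged against the spread between replicates for levels and shares. Ratios have no such spread and were judged against the SD of the medians of matched random lists. By these yardsticks 180 values moved by less, 81 of them ratios, and 134 by more, 17 of them ratios. The 180 include levels and shares with a replicate left out. Those lie within the spread between replicates by construction and say nothing on stability. A change of sign occurred in 1 called value, the -0.10 above, and in 3 levels and 9 ratios of lists not called. A sign under the ratio of TPM + 1 is no direction, since that setting shifts abundant genes together. Leaving out a replicate gives no value for the coefficient of variation or for ratios, and rescaling over protein-coding genes gives none for 3 non-coding lists. No paired analysis was possible because there is 1 group. Depth limits the genes near 0, since 3 counts of Il12a correspond to 0.157 and 0.121 TPM and its credibility intervals reach 0.633 and 0.505.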

Other observations

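All values in this part were picked out after the result was seen, apart from the levels of preset lists. Proliferation genes were low against detected genes, with 7 of 15 detected and a median over all 15 of 1.26 ± 0.42 TPM at percentile 0 of random lists of detected genes. Those lists hold only genes of at least 1 TPM, so this percentile is low largely by construction. Mki67, a marker of cycling cells, was an exception at 53.4 ± 10.8 TPM, with 12811 and 12575 expected counts. Pcna, the replication clamp gene, had 23.3 ± 10.7 TPM, while the topoisomerase gene Top2a had 4.40 ± 0.21 and the mitotic genes Cdk1, Ccnb1 and Plk1 had 1.52 ± 0.88, 1.00 ± 0.21 and 0.475 ± 0.021. Xist, expressed from the inactive X chromosome, had 137212 and 125249 expected counts. The 4 Y-linked genes had a median of 0 TPM in both libraries, with 1 expected count of Kdm5d in replicate 1 and 0 of Ddx3y, Uty and Eif2s3y. The FASTQ-derived tables, however, gave Uty 2.05 and 2.86 TPM and Kdm5d 2.07 and 1.67. The labels give the sex as not collected.

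The interferon gene Ifnb1 had 17.9 ± 4.7 TPM. The receptor genes Lilr4b and Lilrb4a, neighbours on chromosome 10, had 2275 ± 368 and 1895 ± 323 TPM, and the class I histocompatibility gene H2-K1 1656 ± 337.

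Reads were divided differently in the replicates between near-identical models. The mitochondrial mt-Nd4l had 7523 expected counts in replicate 1 and 2178 in replicate 2, and the chromosome 1 pseudogene Gm10222, which holds the same 31-mers, 6588 and 13011. Together they had 14111 and 15189, a log2 ratio of 0.19. The pseudogene Gm28439, whose 31-mers all occur in mt-Nd4, had 22231 and 62987, and the pair summed had a ratio of 0.45. Eif4a-ps4, with 97.4% of its 31-mers in Eif4a1, had 31.5 and 202 counts, and that pair summed had -0.08.

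B430305J03Rik, on the minus strand, shares 100% of its 31-mers with Rap2b on the plus strand, all in reverse complement, and its only other match was 14 in Rap2a, also reversed. In replicate 2 the alignment-based table gave it 366.9 counts and Rap2b 4128.1, which sum to 4495. Both FASTQ-derived tables gave it 0 TPM. Gm42418, annotated as a lincRNA, shares 67.4% of its 31-mers in reverse complement with the ribosomal RNA model CT010467.1 and had 42725 and 35308 expected counts.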
